A study of Schizosaccharomyces pombe with 4 samples.

How the data were processed

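The series compared the genomes of 2 strains of the fission yeast Schizosaccharomyces pombe, named PN1 and PN1400 in the labels. Genomic DNA from exponentially growing, asynchronous cultures was labelled with a green dye (Cy3) or a red dye (Cy5) and hybridised competitively to 2-colour comparative genomic hybridisation arrays, per the labels' protocols. Such an array reports, for each short genomic probe, how much more DNA one sample holds than the other. The labels give 4 arrays in 2 replicates. Each replicate was a dye swap, with 1 array that carried PN1400 in Cy5 and 1 that carried PN1400 in Cy3. The file headers put both arrays of replicate 1 on slide 1 and both arrays of replicate 2 on slide 2, so slide and replicate cannot be told apart, and each slide holds both dye orientations. Nothing in the labels says whether the replicates came from separate cultures, so p-values rest only on the spread between these samples, which may be technical. The limma test used below draws that spread in part from all probes or genes. A low p-value therefore does not show that the 2 replicates agree at a given probe or gene.

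The deposited scanner files held spot intensity values made with Agilent Feature Extraction 10.7.3.1, per the submitters' processing notes. Per the file headers, the processed intensity of each channel was background-subtracted with spatial detrending, corrected by multiplicative detrending and scaled by a linear dye normalization, with no lowess term. The deposited log10 ratio of each spot is that of red over green processed intensity, per the file headers, and recomputing it from the 2 intensities gave differences of at most 4.2e-07. The authors' value table of the same arrays held a linear ratio. Set against the scanner files on the log2 scale, it was the ratio of PN1400 over PN1 without centring, and it differed from the recomputed values by at most 2.8e-07. Its column medians were 0.995 and 1.01 for the arrays of replicate 1 and 0.993 and 1.00 for those of replicate 2. It lacked 66 mitochondrial probes and was used as an alternative.

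For every probe the log2 ratio of PN1400 over PN1 was computed from the processed intensities, with the direction taken from the dyes in the labels, and each array was centred on its median. No loess or quantile normalization was applied. Of 42707 probes, 800 that carried a non-uniformity or population outlier flag on any array were left out, and 41907 were used. Saturated spots were kept. The median distance between neighbouring probes was 267 bp. The 2 arrays of each replicate were averaged, which cancels a dye effect, so n = 2 throughout. The number of arrays limits the precision of every value. Probes not well above background in the PN1400 channel numbered 0 and 1 on the arrays of replicate 1 and 10 and 13 on those of replicate 2.

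The mean profile of the 2 replicates was divided along each chromosome by penalised least squares (PELT, with a penalty of 10 times the noise variance times the logarithm of the number of probes, and a minimum of 5 probes). A segment was called gained or lost when its median was at least 0.4 in size on the log2 scale in the mean and in each replicate. No p-value is given per segment: with 2 replicates the smallest two-sided p of an exact sign permutation is 0.5. Size was taken as the distance from first to last probe, and the gained segment with the most probes is described beside the longest one, a choice made after the segments were seen. Probes and genes were tested with limma 3.58.1 in R 4.3.3 (lmFit with an intercept on the 2 averaged replicates, eBayes, Benjamini-Hochberg adjustment), and were called at an adjusted p under 0.05 and a log2 ratio of at least 0.4 in size. A gene's value was the median over the probes whose midpoint lay in it, for 4350 genes. These designs, the alternatives and the gene lists were fixed before the data were examined, except where stated.

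On simulated profiles of the PN1400 against PN1 comparison over 41907 probes, the segmentation recovered 204 of 204 planted segments, each within 1 probe, with 0 false ones. Values for 4350 genes of the same comparison were simulated too. There limma recovered 100 of 100 genes changed by 0.5 and 100 of 100 changed by 0.9 on the log2 scale, with 0 false calls. The simulated noise was limited to sizes below the calling threshold, so the counts of 0 false segments and calls were fixed in advance. They do not measure how often false calls arise on the arrays. The same limit left out drops as deep as those seen in replicate 1 alone on chromosome II.

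Coordinates are those of the array files, whose headers name a build of NCBI from 2002. Gene annotation came from the assembly ASM294v3, a later build. Whether the coordinates match was checked through the relation of probe length to the reference's base composition at the same position. This correlation, across probes within bins of 100000 bp, had a median of -0.57 over 108 bins. These lay on chromosomes II and III, the mitochondrial chromosome and chromosome I up to 3700000. In every nuclear bin among them it lay at -0.45 or below, a limit that was not taken for the mitochondrial chromosome. Further along the right arm of chromosome I the correlation was -0.03, against -0.61 at an offset of 6151 bp. The first stretch past 3700000 was not included in these values. The 6236 probes past 3700000 were kept in the segmentation and the probe test but were given no gene name, and no coordinates were converted. Probe sequences were read from the reference at the matching positions and searched against it with BLAST 2.17.0, which found another site with at least 85% of the probe identical for 84 of 36471 probes.

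Genes were named by a fixed rule: for each called segment, the first and last gene wholly inside and the nearest gene outside each edge; members of 13 fixed lists that lay in a called segment or passed the gene test; the 10 highest and 10 lowest genes past the test with the same direction on all 4 arrays; and every auxotrophic marker gene. Other genes named in the text were chosen after their values were seen. The alternatives were normexp background correction (offset 50) with and without loess, the deposited value table, centring on the mode, only probes well above background on all arrays, each replicate or dye orientation alone, a correction for base composition, probes with a single match, other penalties, segment minimums and thresholds, a running median of 21 probes, fits on 4 arrays with and without a replicate block, and gene means. The planned normexp setting named mean signals; the median spot and background signals were used in their place. Keeping the 800 probes and testing only genes with at least 3 probes were added after seeing the data.

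The replicate numbers pair the 2 arrays of one dye swap, per the labels and the slides in the file headers. Deviations of the 2 arrays of a replicate from their orientation means correlated at 0.748 across probes, which are not independent replicates.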

Results

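Genomic DNA of the fission yeast strains PN1400 and PN1 was compared on 4 arrays, in 2 replicates of a dye swap each. The title of the series states its purpose as the detection of a duplication in the genome. Across the 41907 probes used, 18608 lay on chromosome I, 15065 on chromosome II, 8182 on chromosome III and 52 on the mitochondrial chromosome. The probe noise (SD estimated from neighbouring probes) was 0.055 on the log2 scale in replicate 1 and 0.078 in replicate 2, and 0.048 in their mean.

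No nuclear chromosome was gained or lost as a whole by the threshold of 0.4. Relative to each array's median, chromosome I had a median log2 ratio of PN1400 over PN1 of 0.0014 ± 0.00040, chromosome II of 0.0028 ± 0.00027 and chromosome III of -0.0023 ± 0.00046 (SD, n = 2). Against this flat background, 6 short segments were called, 4 gained and 2 lost in PN1400. The same procedure gave 1 segment for the difference between the dye orientations, the mitochondrial chromosome, and 4 for the difference between the replicates. There the size was taken as the departure of each orientation or replicate from their average, which is smaller than the full difference. Those between the replicates were the 2 segments called lost, which differed in depth, and stretches of chromosome II that began at 204446 and 1948797.

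**Figure D1:**
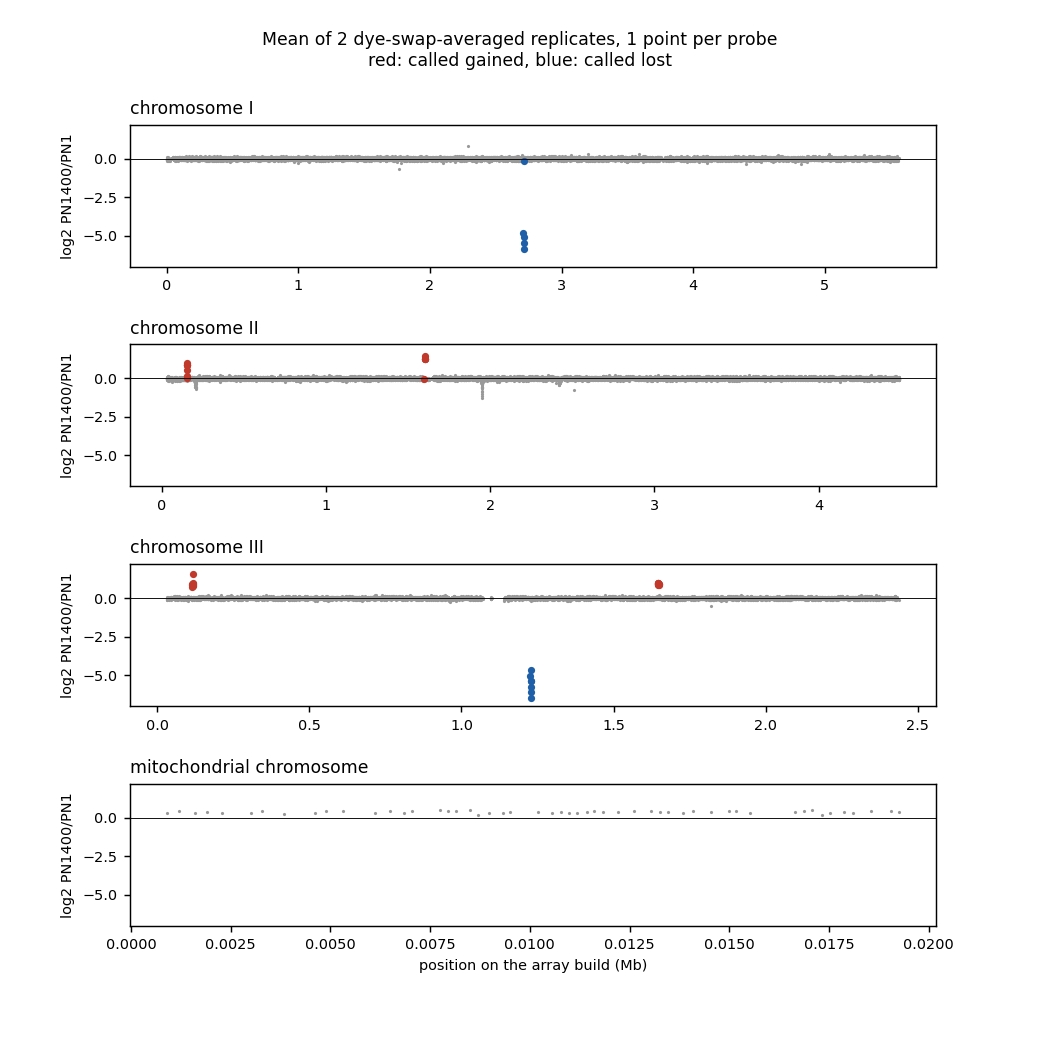
Log2 ratio of PN1400 over PN1 (vertical axis) against position in Mb (horizontal axis), with 1 point per probe, as the mean of 2 dye-swap-averaged replicates. Red points belong to the 4 segments called gained and blue points to the 2 called lost, with 5 and 7 probes, where the signal of PN1400 in replicate 2 was mostly not well above background.

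The title names a duplication, and 4 segments were gained in PN1400. The one with the most probes lay on chromosome III from 1645578 to 1648316, a length of 2739 bp with 10 probes. Its log2 ratio was 0.92 ± 0.016 (SD, n = 2), a 1.89-fold excess, and it was 0.99 and 0.91 on the arrays of replicate 1 and 0.93 and 0.93 on those of replicate 2. With normexp without loess it was 1.31. All 4 gains had higher log2 ratios in that setting, so the folds given for them depend on the background correction. In the main values all 10 probes of this segment exceeded 0.4 and none had another match in the reference. The left edge lay in the coding exon of osr1 (SPCC663.06c) and the right edge in the coding exon of SPCC663.08c. The pseudogene SPCC663.07C lay wholly inside, at 1646645 to 1647396. The last probe on the left without the gain started at 1645362, and the first on the right started at 1648456. The neighbouring genes asf1, which encodes a histone chaperone, and SPCC663.09c had log2 ratios of 0.06 and 0.013. In limma on 2 replicates, SPCC663.07C (log2 0.97 ± 0.014, adjusted p = 6.43e-07) and SPCC663.08c (0.86 ± 0.10, adjusted p = 1.14e-05) were higher in PN1400 on 4 of 4 arrays. The median of osr1, most of whose probes lay outside the segment, was 0.05 (adjusted p = 0.95).

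A second gain on chromosome III, from 115344 to 117114 (1771 bp, 8 probes), contained ura4 (SPCC330.05c), a gene of uracil biosynthesis that is widely used as a selectable marker. The segment had a log2 ratio of 0.86 ± 0.12 (SD, n = 2), or 1.82-fold. The gene ura4 itself, at 115589 to 116625, had 0.96 ± 0.011 (adjusted p = 6.43e-07 in limma, higher on 4 of 4 arrays). The last probe of the segment, at 117055 in intergenic sequence, was higher still at 1.59 ± 0.15. Neither neighbour was gained: tam14 had a log2 ratio of 0.0089 and new25 one of -0.03.

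On chromosome II, the longest gained segment ran from 1598337 to 1603682 (5346 bp, 5 probes), with a log2 ratio of 1.27 ± 0.089 (SD, n = 2), or 2.41-fold. The probe at 1598337 was at -0.04, and the gain itself was carried by 4 probes between 1601844 and 1603682, at 1.24 to 1.44. All of them lie in intergenic sequence beside a cluster of tRNA genes, of which SPBTRNATYR.02 was the first and SPBTRNAASP.05 the last wholly inside the segment. SPBTRNAMET.05 and SPNCRNA.363 were the nearest genes outside it. No probe of the segment lay in a tRNA gene, so whether the tRNA genes were gained was not measured. To the right the next probe lay at 1620842 and was at -0.12, so the right edge lies before it but is not resolved. The left edge is not resolved either, as no probe used lay between those at 1598337 and 1601844. With a minimum of 3 probes the segment measured 1839 bp, and with normexp without loess it reached 19058 bp. The call of 19058 bp began at 1601844 and took in the probe at 1620842, which was not gained in the main values.

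The fourth gain, also on chromosome II, lay within the maltase gene mal1 (SPBC1683.07), from 153604 to 155316 (1713 bp, 7 probes), with a log2 ratio of 0.84 ± 0.018 (SD, n = 2), or 1.79-fold. The gain was interrupted: 5 of the 7 probes, all in the coding exon, were at 0.57 to 0.97, while those at 154055 and 154216, also in the coding exon, were at 0.018 and 0.13. Over all 10 of its probes mal1 had a median of 0.36 ± 0.087, with an adjusted p of 0.00472 in limma but below the size threshold of 0.4. The nearest genes, urh1 and the hexose transporter gene ght4, were at 0.04 and -0.02.

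**Figure D2:**
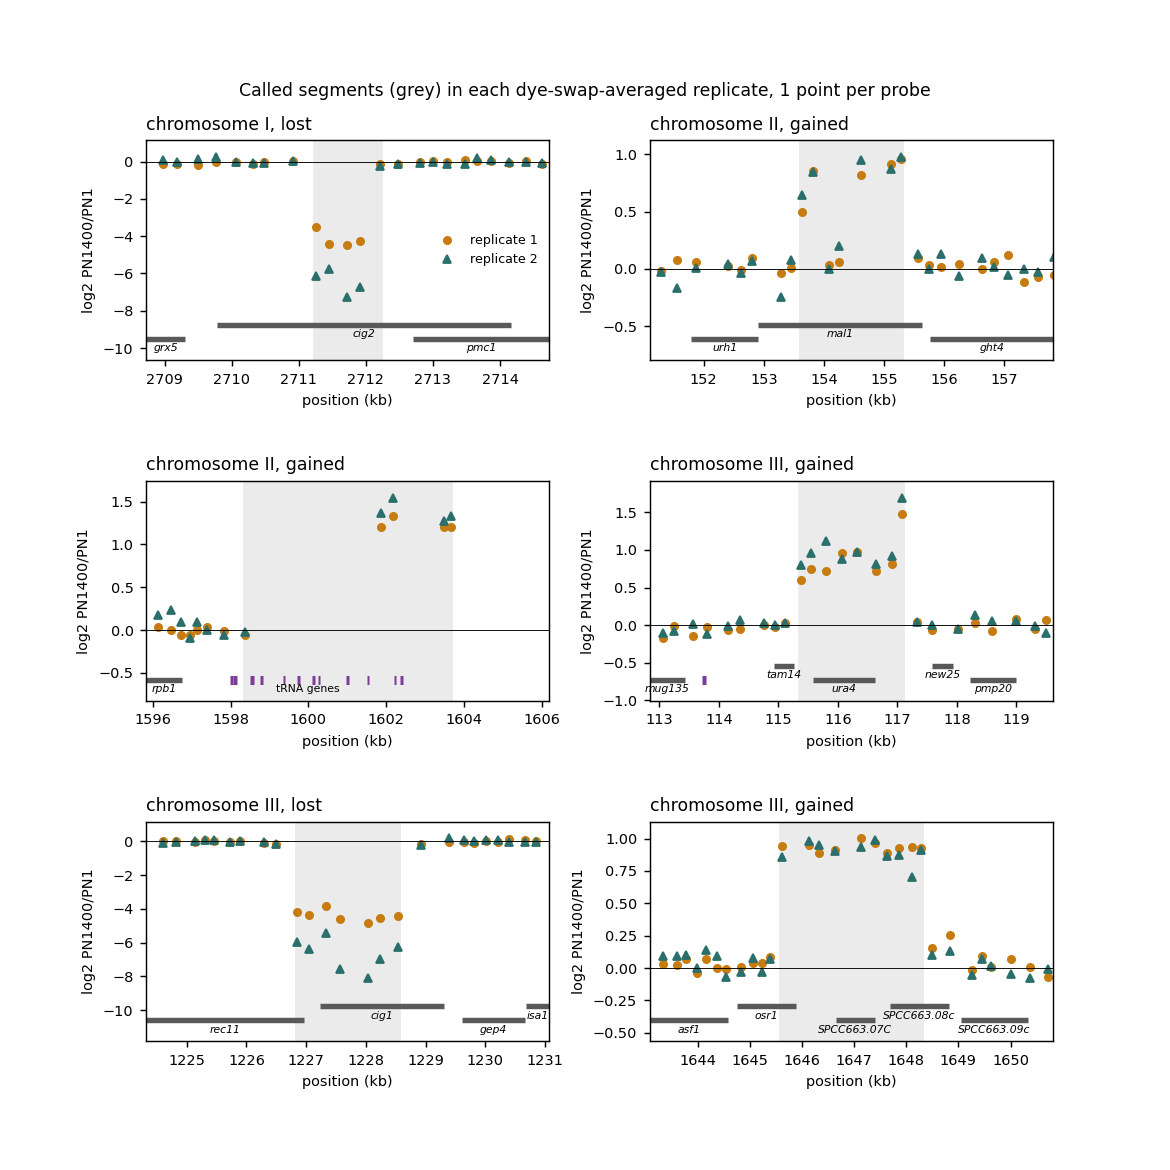
Log2 ratio of PN1400 over PN1 (vertical axis) against position in kb (horizontal axis) at the 6 called segments, shaded grey, with circles for replicate 1 and triangles for replicate 2, each the average of a dye swap. Dark bars are annotated genes and purple bars tRNA genes; the same probes depart from 0 in both replicates, and the median of the loss at cig1 was -4.45 in replicate 1, while in replicate 2 its probes were not well above background in PN1400.

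The losses were at 2 B-type cyclin genes, cig1 and cig2. On chromosome III, 7 probes from 1226822 to 1228569 (1748 bp) had a median log2 ratio of -4.45 in replicate 1. The depth depends on the background correction: the mean of the 2 replicates was -5.41 with the processed intensities and -2.40 with normexp without loess. Both means include replicate 2, whose PN1400 signal was not well above background there. The lost probes covered part of cig1 (SPCC4E9.02, 1227226 to 1229303) and the adjoining end of rec11, a meiotic cohesin gene, at its coding exon. Every probe used in the coding exon of cig1 was lost. The probe of cig1 that was not lost, at 1228897, lay in an untranslated or non-coding exon. The gene cig1 was lower on 4 of 4 arrays (adjusted p = 0.000284 in limma), with a log2 ratio of -4.50 in replicate 1, and rec11, with 13 probes of which most lay outside the loss, had -0.0038. The flanking genes rei1 and gep4 had log2 ratios of -0.0017 and 0.03. Restricting the analysis to probes well above background on all arrays removes the lost probes and ends the calls at cig1 and cig2.

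On chromosome I, 5 probes from 2711226 to 2712234 (1009 bp) in the coding exon of cig2 (SPAPB2B4.03, 2709782 to 2714162) had a median of -4.28 in replicate 1. The mean of the 2 replicates, which includes the low signal of replicate 2, was -5.21 with the processed intensities and -1.36 with normexp without loess. The loss was carried by 4 probes, at -3.51 to -4.45 in replicate 1, and the last probe, at 2712176, was at -0.12 there. As 17 probes lie in the annotated gene, the gene median of cig2 was -0.06 and did not pass the test (adjusted p = 0.95 in limma). The nearest probes on either side of the segment lay in untranslated or non-coding exons and were not lost. The gene median therefore does not describe the coding exon. The neighbours grx5 and pmc1 were at -0.04 and 0.0065. In replicate 1 the PN1400 signal was well above background at the lost probes on both arrays, except at 1 probe of cig1 on 1 array, while in replicate 2 all 7 probes at cig1 on both arrays, and 3 and 4 of the 5 at cig2, were not. The values of replicate 2 there are therefore close to a lower limit of the measurement. Those values enter the means of the 2 replicates and limma's test of cig1, which therefore do not set the depth of a loss. No fold is given for either loss.

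At the level of single probes, 49 were higher and 37 lower in PN1400 in limma, against 89 called in either direction for the dye orientation in a fit of 4 arrays, with the size taken as each orientation's departure from their average. Of the higher probes, 27 lay in the called segments and 21 were mitochondrial. Of the lower probes, 11 lay in the called segments, and 24 passed -0.4 in replicate 1 alone. At the level of genes, 3 of 4350 were higher (SPCC663.07C, ura4 and SPCC663.08c) and 1 was lower (cig1), and 202 had an unadjusted p under 0.05. A fit of 4 arrays with a dye term and the replicate block gave 3 higher and 3 lower genes, the added ones being lsd90 (log2 -0.82) and wwm2 (-0.60).

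Those 2 genes lie in regions of chromosome II that were lower in replicate 1 and not in replicate 2, so they are no difference between the strains that both replicates show. From 201180 to 207847, around wwm2, the median was -0.69 in replicate 1 and 0.03 in replicate 2. From 1947449 to 1952222, around lsd90, it was -1.12 and 0.02, with a lowest probe of -2.53 at 1949713. From 2418612 to 2423118, over sgf29 and hob1, it was -0.65 and 0.02. Both arrays of replicate 1, with dyes swapped, were lower in each region. These genes were chosen after their values were seen. In limma on the 2 replicates lsd90 had -0.82 ± 1.21 and wwm2 -0.58 ± 0.92 (adjusted p = 0.95 for both).

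**Figure D3:**
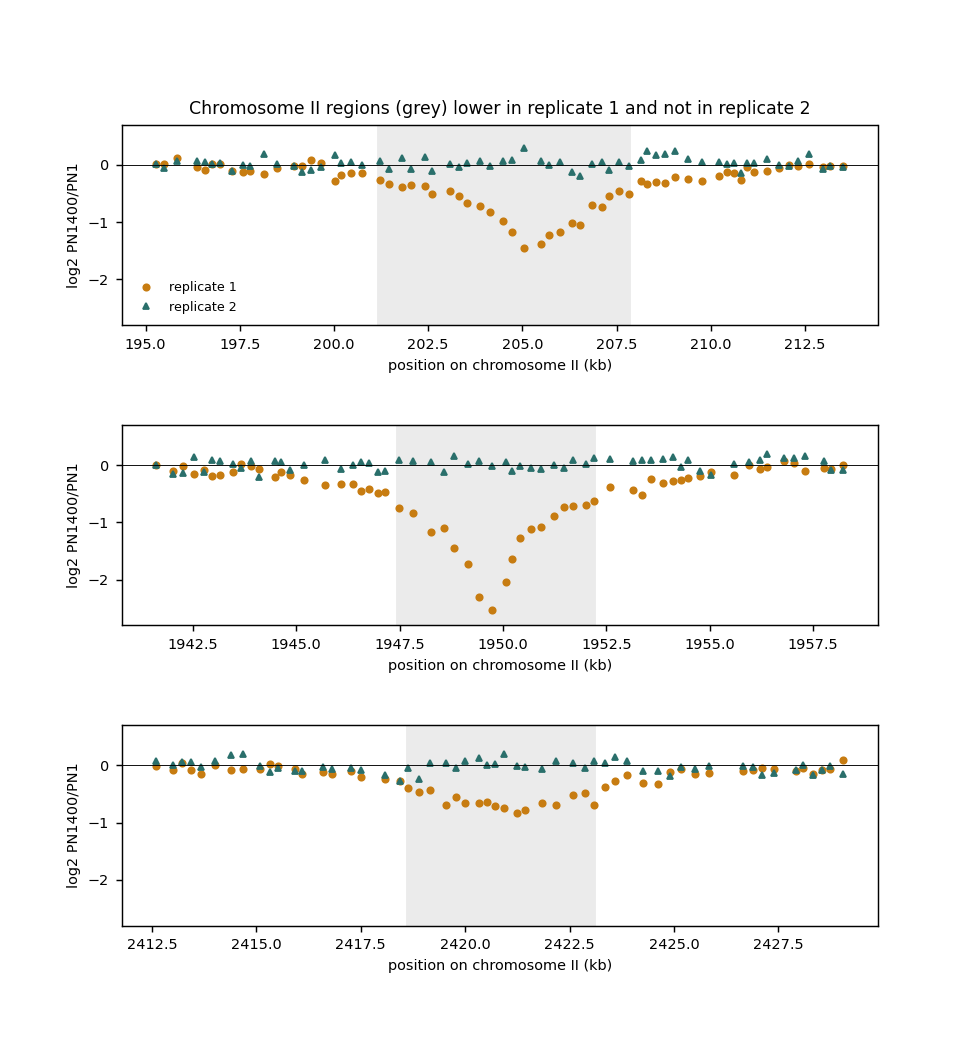
Log2 ratio of PN1400 over PN1 (vertical axis) against position in kb (horizontal axis) in 3 regions of chromosome II, with circles for replicate 1 and triangles for replicate 2, each the average of a dye swap. In the regions shaded grey the lowest probes of replicate 1 are at -1.45, -2.53 and -0.83, and the medians of replicate 2 are 0.03, 0.02 and 0.02.

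Of the auxotrophic marker genes, 12 of 15 were measured, and the gene ura4 alone passed the test (1 higher, 0 lower, and the same when adjusted over the list alone). The other 11 lay between -0.07 (ura5) and 0.07 (lys3), among them leu1 (-0.00046), ade6 (0.018), ade1 (0.03), ade7 (-0.01), his3 (0.03), his5 (-0.02), his7 (-0.03), arg3 (-0.01) and trp1 (0.01). The genes lys1, his1 and ade2 lie on the part of chromosome I without gene names here. Among regulators of the cyclin-dependent kinase and of mitotic entry, 27 of 31 were measured, 1 was lower (cig1), and 1 when adjusted over the list alone. The kinase gene cdc2 (-0.0098), the mitotic cyclin gene cdc13 (0.03), the cyclin gene puc1 (-0.01) and the mitotic inducer gene cdc25 (-0.02) did not pass the test. Over the 26 members not called, values ran from -0.06 (cig2) to 0.07 (mcs6). The value of cig2 is the median over the annotated gene, which the lost probes in its coding exon did not move past the threshold.

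In the other lists 0 genes were called in limma, over all genes or adjusted over the list alone. These were 29 measured genes of DNA replication and repair (the lowest at -0.08, for sld3), 8 of histones and the centromere protein, 13 of the wtf meiotic drive family, 16 subtelomeric genes, 8 hexose transporters, 6 flocculins, 3 ribosomal RNA genes and 9 genes amplified under selection. Of the last group, pmd1 and bfr1, which encode drug efflux transporters, were at -0.0026 and 0.03. Among the mating-type genes and the Tf2 retrotransposons 0 were measured, and the mitochondrial genes were measured as a chromosome only.

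The mitochondrial chromosome had a median log2 ratio of 0.38 ± 0.073 (SD, n = 2), a 1.30-fold excess in PN1400, which stayed below the threshold for a gained segment. This value is an average of opposite orientations that differ: with PN1400 in Cy5 it was 0.91 and 0.87, and with PN1400 in Cy3 it was -0.27 and -0.0011. With PN1400 in Cy3 alone the sign of the mean turned, to -0.14.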

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

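The comparison of the mitochondrial probes between dye orientations was made only after the values were seen. The strain contrast of the mitochondrial probes differed between the orientations by 1.01 on the log2 scale (median of PN1400 in Cy5 minus PN1400 in Cy3), and 52 of 52 probes passed limma's test of the dye term in the fit of 4 arrays with the replicate block. Outside the mitochondrial chromosome 933 probes passed the same test with a full difference between orientations of at least 0.4. The count of 89 probes in the report takes the smaller departure of each orientation from their average as the size. Across probes outside the called segments, arrays of the same orientation correlated at 0.44 and 0.40, while the 2 arrays of a dye swap correlated at -0.09 in replicate 1 and 0.09 in replicate 2. Arrays of opposite orientation from different replicates correlated at -0.46 and -0.37.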

How the results depend on the processing

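Keeping the 800 probes and testing only genes with at least 3 probes were chosen after the data were seen; the other alternatives were planned. Against the main values, 232 results of the comparisons kept their side of the threshold or stayed within the spread, 62 moved and 1 reversed; the cause was not tested except where the construction shows it. The gains at ura4 and between osr1 and SPCC663.08c were called in 18 of 19 alternatives, all but the running median of 21 probes, whose window is wider than these segments.

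With a minimum of 10 probes 2 gained segments and 1 lost one were called, and with the running median 0 of either, so the length and log2 ratio of a gained segment have no value there; the longest one has none with a minimum of 10 probes either. Only probes well above background gave 0 lost segments and 0 lower genes. Normexp without loess raised the log2 ratio of the longest gain to 1.80 and of the one with the most probes to 1.31, and with loess they were 1.82 and 1.32. The gains at ura4 and mal1 were 1.23 and 1.09 without loess and 1.25 and 1.08 with it. As means of the 2 replicates, the losses at cig1 and cig2 were -5.41 and -5.21 in the main setting. They became shallower, at -2.40 and -1.36 without loess and -2.41 and -1.37 with it, and stayed called. The gain at mal1 was 0.76 with PN1400 in Cy3 alone. The gain that was longest in the main values measured 19058 bp under normexp without loess and with PN1400 in Cy3 alone. With a minimum of 3 probes it measured 1839 bp, and the gain with the most probes, at 2739 bp, was longer. The calls of 19058 bp took in the probe at 1620842, which was at -0.12 in the main values. The gain with the most probes was 0.96 with PN1400 in Cy5 alone. The mitochondrial median was 0.89 with PN1400 in Cy5 alone and reversed to -0.14 with PN1400 in Cy3 alone.

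The medians of chromosomes I, II and III, whose replicates differ by under 0.001, were 0.0091, 0.011 and 0.0040 under normexp without loess, 0.00086, 0.0017 and -0.0036 with loess, -0.0045, -0.0030 and -0.0082 when centred on the mode, 0.0020, 0.0024 and -0.0028 after the base composition correction, -0.0010, -3.7e-05 and 0.0013 with PN1400 in Cy5 alone, and 0.00077, 0.0034 and -0.0079 with PN1400 in Cy3 alone.

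Higher and lower probes numbered 16 and 4 under normexp with loess, 28 and 37 with the deposited ratios, which lack 66 mitochondrial probes, 71 and 60 at a threshold of 0.3, 27 and 24 at 0.6, and 89 and 83 by adjusted p alone. With PN1400 in Cy5 alone 163 were higher, and with PN1400 in Cy3 alone 100 were lower. The fit of 4 arrays with no replicate block gave 12 lower probes, and the fit with the replicate block gave 49 higher and 37 lower probes and 3 lower genes; the block changed no other count of calls by over 1.5 times. Gene means gave 3 lower genes, and PN1400 in Cy3 alone gave 2. Leaving out 1 replicate, which fits the 2 arrays of the other and so measures technical spread, gave 28 to 38 higher and 13 to 75 lower probes, 3 to 5 higher and 1 to 10 lower genes, and 2 to 9 lost segments; the higher counts of losses came without replicate 2. Of single genes, 454 values kept their side of the threshold, 6 crossed it upward (mal1 in 4 settings, at 0.42 to 0.51, cig2 and rec11 as gene means) and 1 downward (cig1 without its lost probes). Signal over background in replicate 2 and the background correction limit how deep the losses can be said to be.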

Other observations

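The tests of the direct repeats, of shared signal, of the restriction sites and of the shape of the regions lower in replicate 1 were chosen after the results were seen; those of the separate channels were chosen before their result was seen. Outside the called segments, 2 nuclear probes passed limma's test with at least 0.4 in size in both replicates. The one at 2287928 on chromosome I, in the coding exon of SPAC4G9.19, was at 0.86 ± 0.085 (SD, n = 2, adjusted p = 5.63e-27), while the gene as a whole had a median of 0.06. The other, at 1820300 on chromosome III in the coding exon of the nuclear pore gene nup60, was at -0.51 ± 0.11 (adjusted p = 1.83e-12), with a gene median of -0.03.

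The edges of the gain on chromosome III between osr1 and SPCC663.08c lie in 2 related sequences. In ASM294v3, 918 bp from 1645122 to 1646036 and from 1648007 to 1648923 align in the same orientation with 92.2% identity, at a distance of 2885 bp. The probes at the edges allow a gain of 2739 to 3034 bp, so recombination between these direct repeats, which would add exactly one such distance, may have produced it as a tandem copy. Signal shared between the repeated genes is argued against at the 4 probes of the gain that lie outside every aligned repeat, the lowest of them at 0.88; at the other 6 it was not tested. No junction sequence was measured, so the arrangement and place of the extra copy stay open.

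The gain at ura4 has edges near restriction sites. A HindIII site lies at 115345 in the left edge interval, and 2 lie in the right one, at 117103 and 117148, for fragments of 1758 or 1803 bp. The last gained probe, from 117055 to 117114, runs past the first of these. In all, 2.68% of 10000 random interval pairs of the same sizes and spacing held a site in both. Whether the gain is made of copies of a HindIII fragment that holds ura4 stays open. Equal copies of 1 fragment would raise its probes alike, but the last probe was at 1.59 ± 0.15 (SD, n = 2) and the other 7 at 0.70 to 0.97. Only this enzyme was searched, and the place of the copy was not measured.

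The regions of chromosome II that were lower in replicate 1 alone were lower mainly in the PN1400 channel. Within each dye, slide 1 over slide 2 had a median of -0.73 in that channel over the regions and 0.030 in the PN1 channel, which argues against extra DNA in the PN1 sample as the whole cause and is consistent with fewer copies of these regions in the PN1400 DNA of replicate 1. At lsd90, from 1949142 to 1950259, the PN1 channel was lower too, at -0.35 in Cy3 and -0.63 in Cy5, against -2.67 and -2.50 in the PN1400 channel, and from 1947449 to 1948848 it was at -0.22 and -0.38 against -1.60 and -1.56. For both stretches the SD of random windows in the PN1 channel was 0.14 in Cy3 and 0.17 in Cy5, so these shifts exceeded it. The PN1 channel was higher from 1950372 to 1952222, at 0.26 in Cy3 and 0.10 in Cy5 against -0.76 and -0.69, from 201180 to 203909, at 0.20 and 0.11 against -0.37 and -0.37, and at hob1, at 0.12 and 0.11 against -0.47 and -0.50. The SD of random windows in the PN1 channel was 0.11, 0.10 and 0.08 in Cy3 for these stretches in turn. In Cy5 it was 0.14, 0.13 and 0.10, so the shifts in Cy5 were near that spread. A part played by the PN1 sample stays open there. In the 2 other stretches it was at -0.17 to 0.03. Whether a deletion with fixed ends in a share of the cells lies behind the regions is open too. The SD across probes was 6.50 times the probe noise at wwm2, 10.5 times at lsd90 and 2.27 times at hob1, but the first 2 regions join stretches called at different levels, and the loss at cig1 had 5.79 times the noise in replicate 1. Whether the loss arose in the culture or in the extraction of the DNA was not tested.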
